A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

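Steady-state RNA of budding yeast (Saccharomyces cerevisiae) was measured by RNA sequencing in 15 libraries from 11 genotypes. Per the labels' protocols, cultures were grown to mid-log phase in rich medium, RNA was extracted with hot phenol, ribosomal RNA was depleted and libraries were made with an Illumina TruSeq kit. The wild type and the htz1, xrn1 and upf1 deletions had 2 libraries each, and each of the other 7 genotypes had 1. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

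The authors deposited a table of RPKM values (reads scaled by gene length and library size) with 6662 entries. STAR 2.4.0, CASAVA and the sacCer3 build are named in the submitters' processing notes. The read counter, the annotation and the strand setting are not given in the sources used here. The values themselves were checked for what 1 read is worth. RPKM multiplied by the length of the whole gene gave whole numbers of reads, within 0.1 read, for 99.7 to 99.8% of the low values in each library, where chance gives 20%. The implied library totals lay between 7160196 and 57373635 reads. For genes with introns the whole gene length gave whole reads for at least 98.9% of the low values, and the summed exon length for at most 26.4%. RPKM was therefore scaled by the length of the whole gene, which does not show whether reads in introns were counted. Either way, these values do not separate spliced from unspliced RNA. For 20 of 21 pairs of genes that overlap on opposite strands, the values lay within 2-fold of each other, so reads of a gene and its antisense partner were not separated. Gene identifiers were matched to the R64 reference annotation, the same build as sacCer3: 5986 matched and 673 did not and were kept under the deposited name. Left out were 3 entries without a distinct name, which held 0.0203 to 0.129% of the summed RPKM of a library, and 1 column that matched no sample.

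Changes were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend on mean expression) on log2(RPKM + 1), which understates the change of low genes. Tested were the 6495 genes with a mean of at least 1 RPKM over the 15 libraries, with the values used as deposited. Comparisons with the wild type and the interactions were taken from a model with one mean per genotype over all 15 libraries and 4 residual degrees of freedom, in which a lone library is assumed to vary like the replicated genotypes. The htz1 deletion was also averaged over 4 backgrounds (wild type, xrn1, upf1 and prp43 DAmP; 5 libraries without HTZ1 against 7), with background as a term and 7 residual degrees of freedom. The swr1 deletion was averaged over 3 backgrounds (3 libraries against 6; 5 residual degrees of freedom). The htz1 and swr1 deletions were compared directly over the same 3 backgrounds (4 libraries against 3; 3 residual degrees of freedom). A call is a Benjamini-Hochberg adjusted p under 0.05, and values after ± are standard errors of the log2 change unless an SD is named. Where the median of all genes lay more than 0.1 from 0 on the log2 scale and moved by more than 0.1 on rescaling, gene values are given relative to that median, and the tests are those of the unshifted values.

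Gene lists of pathways, complexes, strain markers and genome regions were fixed, and 35 of 40 had at least 5 measured members. They were tested against all other genes with camera at a preset correlation of 0.01 and with an estimated correlation, and by themselves with fry, with adjustment over the 35 lists. A list value is the median log2 change of its members minus that of the other genes. Genes were named by rule: among called genes that moved the same way in every library, the 10 largest rises and 10 largest falls (5 each for the swr1 and prp43 comparisons, the direct comparison and the interactions), and up to 4 called members of each list. The altered genes, strain markers and mating-type lists were reported by themselves, and in a comparison with no call the 3 genes with the smallest p each way were named. The groups, tests, thresholds, lists, naming rule and most alternatives were fixed before the data were examined.

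Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 RPKM, scaling of each library to the same median log ratio, a prior variance without a trend, the replicate number as a block, fits to the compared libraries alone, an additive model of all 15 libraries, and leaving out each library in turn. Chosen after seeing the data were limma voom on the recovered reads and fits that leave out, keep only or adjust for libraries rich in ribosomal DNA (rDNA) sequence. The procedure was tested on simulated data: 5 sets with 200 changed genes of 1.5, 2 or 4-fold. At 4-fold it recovered 86.4% for htz1, 87.3% for xrn1, 90.3% for upf1, 67.6% for swr1 and 73.9% for prp43 DAmP against the wild type, and at 2-fold 21.2%, 20.3%, 20.3%, 4.18% and 4.78%. For the averaged comparisons the 2-fold recovery was 86.3% (htz1), 82.7% (swr1) and 71.9% (htz1 against swr1), and for the interactions the 4-fold recovery was 28.2% (xrn1), 22.1% (upf1) and 1.52% (prp43 DAmP). False calls averaged 0.6 to 9.8 per set. The simulated noise was independent between genes, with as many rises as falls, and lone libraries were given the fitted spread. Differences between libraries that many genes share were not simulated, so false calls in the real data may be more. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.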

Results

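The transcriptomes of 15 yeast libraries were compared to ask how loss of the histone variant H2A.Z (gene HTZ1) or of SWR1, the remodeller that deposits it, changes RNA levels, alone and in strains that retain RNA otherwise degraded. XRN1 encodes the cytoplasmic 5'-to-3' exonuclease, UPF1 (listed as NAM7) the helicase of nonsense-mediated decay, and PRP43 a helicase that releases the spliced-out intron lariat and acts in ribosome assembly. The prp43 DAmP allele is built to lower the PRP43 mRNA. The wild type and the htz1, xrn1 and upf1 deletions had 2 libraries each (the wild-type libraries are numbered 1 and 3), and 1 library each was made from the swr1 deletion, the htz1 xrn1, htz1 upf1, swr1 xrn1 and swr1 upf1 double deletions, prp43 DAmP and prp43 DAmP with the htz1 deletion. Library totals implied by the values ranged from 7160196 reads (swr1 upf1) to 57373635 (prp43 DAmP). Across genes, Spearman's rho between replicates was 0.969 for the wild type, 0.965 for htz1, 0.949 for upf1 and 0.933 for xrn1. Some libraries of different genotypes were at least as alike, such as htz1 2 with prp43 DAmP htz1 (0.992) and wild type 1 with swr1 (0.976). Replicates were thus not always the closest pairs.

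The altered genes followed the labels in every library. HTZ1 (YOL012C, chromosome XV, 303579 to 303983) was listed at 0 in both htz1 libraries, in htz1 upf1 and in prp43 DAmP htz1, and at 0.273 RPKM in htz1 xrn1, against 109 ± 6.97 RPKM (SD, n = 2) in the wild type. SWR1 (YDR334W, chromosome IV, 1135932 to 1140476) lay at 0.0658, 0.0972 and 0 RPKM in the swr1, swr1 xrn1 and swr1 upf1 libraries, against 29.4 ± 9.01 in the wild type. XRN1 (YGL173C, chromosome VII, 175527 to 180113) was at most 0.290 RPKM in its 4 deleted libraries, against 159.9 ± 21.9. NAM7 (YMR080C, chromosome XIII, 426712 to 429627) was at most 0.192 RPKM in the 4 upf1 libraries, against 86.1 ± 16.1. PRP43 (YGL120C, chromosome VII, 281634 to 283937) stood at 42.7 RPKM in prp43 DAmP and 55.4 in prp43 DAmP htz1, below 139 ± 26.4 in the wild type, but the difference for prp43 DAmP (log2 -1.55 ± 0.39, 1 library against 2) did not pass the test (adjusted p = 0.244).

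Libraries also differed in mating type, strain markers and rDNA sequence. MF(ALPHA)1, the alpha-factor pheromone gene of MATalpha cells, stood at 2226, 2942 and 1968 RPKM in the swr1, swr1 xrn1 and swr1 upf1 libraries and at 2262 in wild type 1, and at most at 4.72 in the other 11. STE2, the alpha-factor receptor of MATa cells, was 13.7 RPKM or less in those 4 libraries and at least 219 in the others. Mating type thus coincided with the swr1 deletion in the xrn1 and upf1 backgrounds and differed between the wild-type libraries. MET17, a methionine biosynthesis gene, was at most 0.362 RPKM in xrn1 1, htz1 2, swr1 xrn1, swr1 upf1, htz1 upf1 and both prp43 DAmP libraries, while LYS2, a lysine biosynthesis gene, was 43.5 RPKM or more in 5 of those 7 and at most 0.298 elsewhere. Reading frames in the rDNA repeat, such as TAR1, took 21.2% of the summed RPKM in htz1 1, 16.9% in swr1, 16.1% in htz1 upf1, 14.5% in swr1 upf1 and 12.1% in swr1 xrn1, and 0.0187 to 3.41% in the other 10 libraries. All 3 libraries without SWR1 and 2 of the 5 without HTZ1 were thus rich in rDNA sequence.

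**Figure D1:**
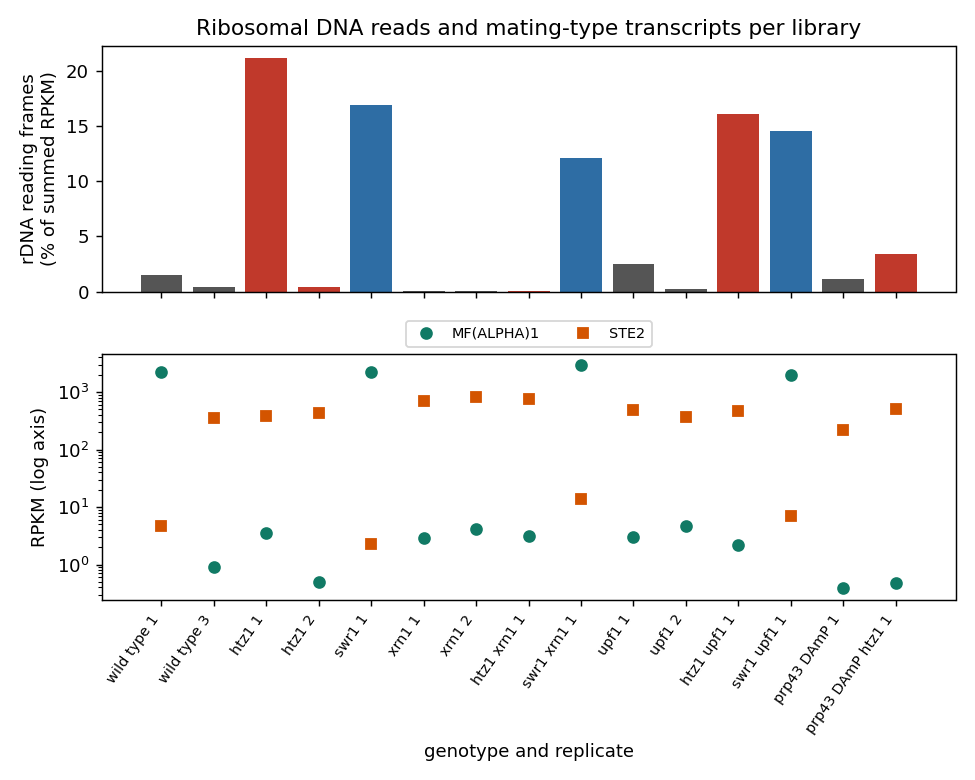
Share of the summed RPKM in rDNA reading frames (upper panel, %, bars) and RPKM of MF(ALPHA)1 and STE2 on a log axis (lower panel, points), per library, with bars in red for htz1, blue for swr1 and grey for other libraries. The share exceeds 10% in 5 libraries, and the 3 swr1 libraries and wild type 1 carry MF(ALPHA)1 at 1968 RPKM or more.

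Loss of HTZ1 in otherwise wild-type cells lowered genes of phosphate supply. PHO84, the high-affinity phosphate transporter, fell from 698 ± 361 RPKM (SD, n = 2) to 33.9 ± 18.7 (n = 2; log2 -4.23 ± 0.51, adjusted p = 0.0214 by limma, relative to a median of all genes of -0.105). PHO11 (log2 -3.51, adjusted p = 0.0209) and PHO12 (log2 -3.41, adjusted p = 0.0214), near-identical acid phosphatase genes whose reads cannot be assigned with certainty, fell as well. With HTZ1 itself these were the 4 calls among 6495 genes, and 302 genes had an unadjusted p under 0.05. In the phosphate (PHO) regulon, 3 of 19 members fell and 16 did not pass (14 fell when adjusted over the list alone). Together the phosphate genes lay at -1.17 (camera adjusted p = 2.61e-25, and adjusted p = 0.663 with an estimated correlation). None of 36 heat shock and general stress genes passed, including SSA1 (log2 0.54), a cytosolic Hsp70, but the list lay 0.53 above other genes (adjusted p = 3.04e-16, and adjusted p = 0.663 with an estimated correlation). None of 38 nuclear respiratory chain genes passed either. Together the respiratory chain genes lay at 0.36 (adjusted p = 1.53e-10, and adjusted p = 0.663 with an estimated correlation). Among 210 genes within 20 kb of a chromosome end, PHO11 and PHO12 fell and 208 did not pass (10 fell when adjusted over the list alone). Together the chromosome-end genes lay at -0.13 (adjusted p = 0.00037, and adjusted p = 0.829 with an estimated correlation). Without wild type 1 only HTZ1 was called and PHO84, PHO11 and PHO12 changed by -3.78, -3.56 and -3.48 (unshifted), without htz1 2 PHO12 was lost at -3.21, without htz1 1 there were 8 calls, and without wild type 3 there were 27 (7 higher). With no filter on low values HTZ1 alone was called. The MATa-specific genes (3.28; adjusted p = 5.17e-10, and adjusted p = 0.663 with an estimated correlation) and MATalpha-specific genes (-2.90; adjusted p = 0.0022, and adjusted p = 0.663 with an estimated correlation) moved with wild type 1, without which the MATalpha value was 0.07.

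Averaged over the wild-type, xrn1, upf1 and prp43 DAmP backgrounds (5 libraries without HTZ1 against 7), the phosphate genes led again. PHO84 (log2 -3.31 ± 0.35, adjusted p = 0.00242) and SPL2, which down-regulates low-affinity phosphate uptake (log2 -3.20 ± 0.36, adjusted p = 0.00304), fell furthest after HTZ1 itself. PHM6 (-2.32 ± 0.34) and VTC3, of the polyphosphate polymerase complex (-1.94 ± 0.28), fell too. PHO84 stood at 18.8 to 129 RPKM in the 5 libraries without HTZ1, at 112 in prp43 DAmP and at 338 or more in the other 9. In the list, 11 of 19 members fell and 8 did not pass (18 fell when adjusted over the list alone). Together the phosphate genes lay at -1.38 (adjusted p = 2.32e-18, and adjusted p = 0.452 with an estimated correlation; fry adjusted p = 0.00622). The mean of the list differed by -1.43, lower than in any other division of the libraries within backgrounds (exact permutation test, one-sided p = 0.00926). This test was chosen after the fall was seen, and its p-value is not adjusted for that choice. Among genes within 20 kb of a chromosome end, 22 of 210 fell and 188 did not pass (42 fell and 1 rose when adjusted over the list alone), the falls including YDR541C (log2 -2.31 ± 0.23, adjusted p = 0.00154). Together the chromosome-end genes lay at -0.24 (adjusted p = 6.1e-08, and adjusted p = 0.788 with an estimated correlation). Of 68 members of subtelomeric gene families 62 did not pass and 6 fell, among them COS7 (-1.12 ± 0.19) and GEX2 (-1.16 ± 0.22), whose reads may be shared with close copies (17 fell when adjusted over the list alone). Together the subtelomeric family genes lay at -0.37 (adjusted p = 8.48e-07, and adjusted p = 0.788 with an estimated correlation). SPS2, a sporulation gene, fell (adjusted p = 0.0462) among 26 meiosis and sporulation genes, of which 25 did not pass (4 fell when adjusted over the list alone). Together the meiosis genes lay at -0.22 (adjusted p = 0.0232, and adjusted p = 0.788 with an estimated correlation), and at -0.13 and not called without htz1 upf1.

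Rises in the same averaged comparison were smaller. CAR2, an arginine catabolism enzyme (log2 1.48 ± 0.33, adjusted p = 0.0462), TIP1, a cell wall mannoprotein (1.48 ± 0.29), and FIT3, a siderophore-binding wall protein (1.37 ± 0.27), were the largest, and SWR1 rose by log2 0.81 ± 0.17, adjusted p = 0.038. FIT3 was the 1 call among 27 iron regulon genes (2 when adjusted over the list alone), and none of 36 heat shock genes passed (4 rose when adjusted over the list alone). Together the iron genes lay at 0.33 (adjusted p = 0.00102, and adjusted p = 0.788 with an estimated correlation). Together the heat shock genes lay at 0.30 (adjusted p = 2.35e-06, and adjusted p = 0.788 with an estimated correlation). In all, 29 genes rose and 96 fell, and 122 of these 125 moved the same way in every library. After each library was scaled to the same median log ratio, 141 rose and 223 fell, and the directions of the phosphate, chromosome-end, iron and heat shock lists were unchanged. PHO84, SPL2, PHM6, VTC3, PHO11, PHO12 and YDR541C kept their calls whichever 1 library was left out, and 25 of the 33 named calls, CAR2, TIP1, FIT3, SWR1, COS7, GEX2 and SPS2 among them, were lost without at least 1 library. The count of calls was 60 without wild type 1, 70 without wild type 3, 66 and 62 without xrn1 1 and 2, 62 and 78 without upf1 1 and 2, 58 without htz1 2, 32 without htz1 xrn1 (1 of them higher), 30 without htz1 upf1 (1 higher), 40 without either prp43 DAmP library (7 higher), and 13 without the 2 htz1 libraries rich in rDNA (0 higher). Higher genes also numbered 9 without upf1 1, htz1 1 or wild type 3, and 21 without wild type 1. An additive model of all 15 libraries gave 268 calls, and 259 with the rDNA share as a term.

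**Figure D2:**
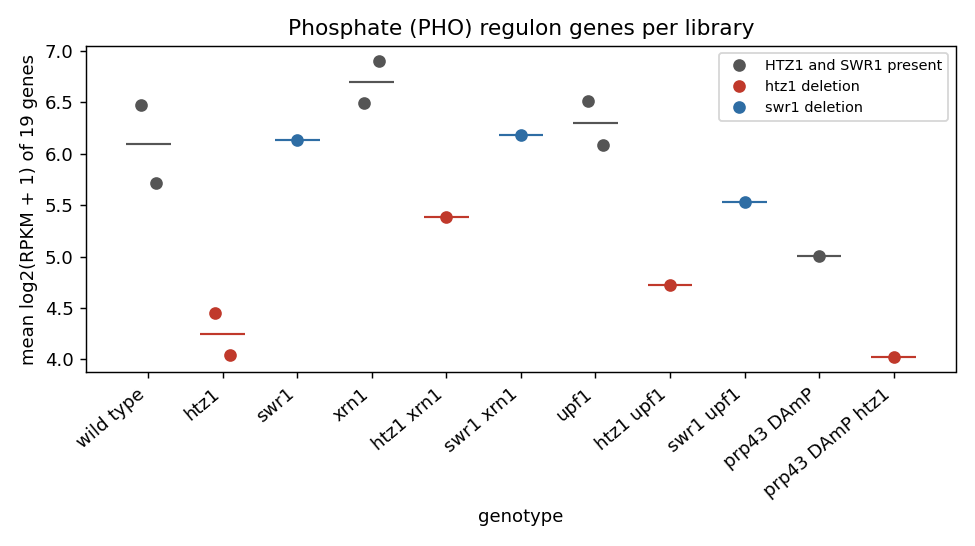
Mean log2(RPKM + 1) of the 19 phosphate regulon genes per library (points) and per genotype (short lines), in red where HTZ1 is deleted, blue where SWR1 is deleted and grey otherwise. The htz1 libraries lie at 4.45 and 4.04 against 6.47 and 5.72 in the wild type, and each library without HTZ1 lies below the libraries of its own background.

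Because H2A.Z was studied here for its part in splicing, genes with introns were tested as a list. Against the wild type none of the 269 passed, including ACT1, actin (log2 0.34), and ASC1, a ribosome-associated protein (-0.14), and the list value was -0.02 (unadjusted p = 0.123, and p = 0.663 with an estimated correlation), or -0.083 (unadjusted p = 0.000471) against genes without introns of matched mean expression. Against all other genes the value was -0.20 without wild type 1, -0.17 without htz1 2, 0.14 without htz1 1 and 0.17 without wild type 3. Averaged over backgrounds, 266 of the 269 did not pass and 3 fell, namely STO1, the large subunit of the nuclear cap-binding complex (log2 -0.84 ± 0.16, adjusted p = 0.03), SPO1, a meiotic gene (-0.68 ± 0.15), and SNC1, a vesicle SNARE (-0.55 ± 0.11), each lost without at least 1 library. The list value was -0.08 (adjusted p = 0.0242, and adjusted p = 0.788 with an estimated correlation), -0.02 (p = 0.193) without the ribosomal protein genes, and -0.0994 (p = 0.000131) against genes without introns of matched mean expression. Scaling ended the call at an unchanged value (unadjusted p = 0.0546). The 89 ribosomal protein genes with introns, none called, lay at -0.12 (adjusted p = 0.000252, and adjusted p = 0.82 with an estimated correlation). By background, that list lay at -0.30 in xrn1, -0.35 in upf1, -0.02 in the wild type and 0.19 in prp43 DAmP, while other genes with introns lay between -0.077 and -0.002. Its call was lost without htz1 xrn1 (-0.08), htz1 upf1 (-0.04) or wild type 3 (-0.04). Without the 2 htz1 libraries rich in rDNA the value of the ribosomal protein list turned to 0.03. Left out 1 at a time, xrn1 1, htz1 1, htz1 xrn1, htz1 upf1 and wild type 3 each ended the averaged call for genes with introns (list values -0.05, -0.03, -0.06, -0.03 and -0.03), and without the 2 htz1 libraries rich in rDNA the value was 0.02. These values do not separate spliced from unspliced RNA, so the list shows the level of these genes and not splicing.

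Loss of SWR1 in otherwise wild-type cells (1 library against 2) lowered YDR541C, a subtelomeric gene encoding a putative reductase, to 0.619 RPKM from 16.1 ± 4.61 (SD, n = 2; log2 -3.27 ± 0.37, adjusted p = 0.0236, relative to a median of all genes of -0.106). SWR1 was the only other call, 283 genes had an unadjusted p under 0.05, and limma voom on the recovered reads called 0 genes with 201 at an unadjusted p under 0.05. None of 68 subtelomeric family genes passed (3 fell when adjusted over the list alone). Together the subtelomeric family genes lay at -0.55 (adjusted p = 4.37e-09, and adjusted p = 0.964 with an estimated correlation). Of 210 genes within 20 kb of an end 1 fell and 209 did not pass (19 fell when adjusted over the list alone). Together the chromosome-end genes lay at -0.29 (adjusted p = 2.34e-08, and adjusted p = 0.964 with an estimated correlation). None of 38 nuclear respiratory chain genes passed. Together the respiratory chain genes lay at 0.31 (adjusted p = 1.27e-09, and adjusted p = 0.964 with an estimated correlation). Without wild type 1 there were 18 calls (9 higher), and with a pseudocount of 5 or with no filter there were 0.

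Averaged over the wild-type, xrn1 and upf1 backgrounds (3 libraries against 6), some genes near chromosome ends were lower in the swr1 libraries. The hexose transporter genes HXT15 (log2 -2.67 ± 0.23, adjusted p = 0.00119) and HXT16 (-2.67 ± 0.24), the sorbitol dehydrogenase genes SOR1 (-2.53 ± 0.23) and SOR2 (-2.54 ± 0.23), each pair near-identical so that reads may be shared, and YDR541C (-2.56 ± 0.33) fell. HXT15 went from 32.1 ± 3.81 RPKM in xrn1 (SD, n = 2) to 2.85 in swr1 xrn1, and from 32.9 and 36.3 in upf1 to 3.44 in swr1 upf1. Of 68 subtelomeric family genes 21 fell and 47 did not pass (33 fell when adjusted over the list alone), the falls including SNZ3, of pyridoxine synthesis (-1.89 ± 0.19), and THI11, of thiamine synthesis (-1.83 ± 0.22). Together the subtelomeric family genes lay at -0.62 (adjusted p = 5.88e-15, and adjusted p = 0.652 with an estimated correlation; fry adjusted p = 0.0265). Within 20 kb of an end 44 of 210 fell, 1 rose and 165 did not pass (77 fell and 2 rose when adjusted over the list alone). Together the chromosome-end genes lay at -0.36 (adjusted p = 1.22e-11, and adjusted p = 0.652 with an estimated correlation). Of 26 meiosis and sporulation genes 6 fell and 20 did not pass (14 fell when adjusted over the list alone), the falls including REC8, the meiotic cohesin (-1.82 ± 0.38), SPO13 (-1.53 ± 0.23) and SPS2 (-1.74 ± 0.27). Together the meiosis genes lay at -0.48 (adjusted p = 4.2e-06, and adjusted p = 0.652 with an estimated correlation). None of 87 ribosome biogenesis genes passed. Together the ribosome biogenesis genes lay at 0.40 (adjusted p = 6.27e-19, and adjusted p = 0.956 with an estimated correlation).

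Reading frames of the rDNA were higher in the swr1 libraries: YLR154W-A (log2 6.66 ± 1.35, adjusted p = 0.0281), TAR1 (6.56 ± 1.29) and YLR154C-G (6.38 ± 1.19). Their share of the summed RPKM was also high in htz1 1 (21.2%) and htz1 upf1 (16.1%), which carry SWR1. These rises therefore cannot be assigned to the swr1 deletion. All 7 MATa-specific genes fell, such as BAR1, a protease that degrades alpha-factor (-4.62 ± 0.77). Of 5 MATalpha-specific genes 2 rose and 3 did not pass (5 rose when adjusted over the list alone). After scaling to the same median log ratio 4 MATa-specific genes were called lower and 1 MATalpha-specific gene higher. Together the MATalpha-specific genes lay at 3.51 (adjusted p = 7.37e-07, and adjusted p = 0.652 with an estimated correlation). Together the MATa-specific genes lay at -4.54 (adjusted p = 4.83e-07, and adjusted p = 0.652 with an estimated correlation). In all 31 genes rose and 229 fell, 253 of the 260 in the same direction in every library. HXT15, HXT16, SOR1, SOR2, SNZ3, THI11 and YDR541C kept their calls whichever 1 library was left out, whereas 24 of the 33 named calls, including REC8, SPO13, SPS2, BAR1 and the rDNA reading frames, were lost without at least 1 library. The count was 43 without swr1 xrn1 (3 higher), 79 without swr1 upf1 (5 higher), 82 without swr1 (5 higher), 150 without xrn1 1 and 153 without upf1 2, and without xrn1 2 9 genes rose and 99 fell. A mean of at least 10 RPKM left 105 calls. An additive model of all 15 libraries gave 364 calls, and 6 with the rDNA share as a term. With that term the 20 kb list stood at -0.23, the family list at -0.49 and ribosome biogenesis at -0.06, none of them called.

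Compared directly over the same 3 backgrounds, the htz1 libraries (n = 4) differed from the swr1 libraries (n = 3) in mating-type transcripts. All 7 MATa-specific genes were higher with the htz1 deletion, among them MFA2, an a-factor gene (log2 7.94 ± 0.32, adjusted p = 0.000156), and STE2 (6.25 ± 0.26; list adjusted p = 2.33e-22, and adjusted p = 0.112 with an estimated correlation). All 5 MATalpha-specific genes were lower, MF(ALPHA)1 and STE3, the a-factor receptor, among them (STE3 log2 -6.84 ± 0.35, adjusted p = 0.000359; list adjusted p = 9.57e-21, and adjusted p = 0.112 with an estimated correlation). YKL177W (-6.98 ± 0.17) and YLR041W (-3.81 ± 0.27) overlap STE3 and AFB1 on the opposite strand and cannot be told apart from them, and HMLALPHA1 (-5.50 ± 0.24) shares its sequence with MATALPHA1. Outside these, SPL2 was lower in the htz1 libraries (log2 -3.51 ± 0.41, adjusted p = 0.0264) and DAN1, an anaerobic cell wall mannoprotein (log2 3.62 ± 0.36, adjusted p = 0.0124), and FIT2, a siderophore-binding wall protein (log2 1.42 ± 0.16, adjusted p = 0.0213), were higher. Of 19 phosphate genes SPL2 fell and 18 did not pass (14 fell when adjusted over the list alone). The mean of the list differed by -1.16 (exact permutation within backgrounds, one-sided p = 0.0833, the smallest that the 12 arrangements allow). This permutation test, too, was chosen after the result was seen. Together the phosphate genes lay at -1.16 (adjusted p = 2.76e-18, and adjusted p = 0.368 with an estimated correlation). Of 27 iron regulon genes FIT2 rose and 26 did not pass (10 rose when adjusted over the list alone). Together the iron genes lay at 0.33 (adjusted p = 2.77e-07, and adjusted p = 0.112 with an estimated correlation). None of 20 trehalose and glycogen genes (10 rose when adjusted over the list alone) and none of 87 ribosome biogenesis genes passed. Together the trehalose genes lay at 0.48 (adjusted p = 2.59e-07, and adjusted p = 0.123 with an estimated correlation). Together the ribosome biogenesis genes lay at -0.46 (adjusted p = 2.96e-22, and adjusted p = 0.681 with an estimated correlation). In all 14 genes were higher and 12 lower, with 17 calls by voom and 146 in only the 5 libraries rich in rDNA (112 higher; 1 residual degree of freedom). SPL2 lost its call without swr1 xrn1 or htz1 xrn1 (-3.85) and without swr1 upf1 or htz1 upf1 (-3.82), DAN1 without swr1 (3.74), and FIT2 without swr1 (1.56) and each of the 4 double deletions (1.36 to 1.37).

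With loss of XRN1 (2 libraries against 2) 3951 genes rose and 269 fell, 3054 and 132 of them by at least 2-fold. The median of all genes rose by 0.96 on the log2 scale, and after scaling to the same median log ratio 1224 genes were higher and 1163 lower, so the gene values that follow are relative to that median. Cell cycle genes rose: PCL1, a G1 cyclin, went from 37.2 ± 0.255 to 520.1 ± 121 RPKM (SD, n = 2 each; log2 2.79 ± 0.28, adjusted p = 0.000388), with CLB6, an S-phase cyclin (2.79 ± 0.35), CDC6, a replication licensing factor (1.62 ± 0.28), and CLB2, a mitotic cyclin (1.29 ± 0.21). All 19 G2/M and M/G1 genes rose, and 20 of 24 G1/S genes rose while 4 did not pass. Together the G2/M genes lay at 0.84 (adjusted p = 9.19e-05, and adjusted p = 0.626 with an estimated correlation), and 14 rose after scaling. Together the G1/S genes lay at 0.36 (adjusted p = 0.0058, and adjusted p = 0.626 with an estimated correlation), and 11 rose and 2 fell after scaling. Of 82 spliceosome genes 70 rose, 1 fell and 11 did not pass, the rises including BUD31 (1.49 ± 0.33) and AAR2 (1.48 ± 0.27). Together the spliceosome genes lay at 0.37 (adjusted p = 0.0019, and adjusted p = 0.944 with an estimated correlation), and 27 rose and 1 fell after scaling. Of 15 telomere maintenance genes 14 rose and 1 did not pass, the rises led by STN1 of the telomere capping complex (1.82 ± 0.24) and EST2, telomerase reverse transcriptase (1.62 ± 0.26). Together the telomere genes lay at 0.59 (adjusted p = 0.0216, and adjusted p = 0.929 with an estimated correlation), and 8 rose and 1 fell after scaling. Of 7 MATa-specific genes STE2 (3.11 ± 1.42), MFA1, an a-factor gene (2.90 ± 1.52), and STE6, the a-factor exporter (2.53 ± 0.97), rose and 4 did not pass, and after scaling none passed. These rises rested on the mating type of wild type 1: unshifted, STE2, MFA1 and STE6 changed by 4.07, 3.85 and 3.49, by 1.07, 0.71 (not called) and 1.49 without wild type 1 and by 7.07, 7.003 and 5.49 without wild type 3. Without xrn1 1 STE2 (4.16) and MFA1 (3.87) lost their calls, and without xrn1 2 STE2 (3.98), MFA1 (3.84) and STE6 (3.28) did. Of 18 decay and decapping genes 10 rose and 8 did not pass, the rises including EDC1, a decapping enhancer (1.54 ± 0.25), and DCP2, the decapping enzyme (0.66 ± 0.25). Together the decapping genes lay at -0.27 (adjusted p = 0.717, and adjusted p = 0.953 with an estimated correlation), and 2 rose and 3 fell after scaling.

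Abundant transcripts went the other way in xrn1. ADH1, alcohol dehydrogenase (log2 -3.14 ± 0.31, adjusted p = 0.000852), ENO2, enolase (-2.90 ± 0.31), and TDH3, glyceraldehyde-3-phosphate dehydrogenase (-2.53 ± 0.30), fell, with 15 of 29 glycolysis and fermentation genes lower, 5 higher, such as HXK1 (1.28 ± 0.49), and 9 not passing. Together the glycolysis genes lay at -1.74 (adjusted p = 2.22e-18, and adjusted p = 0.229 with an estimated correlation), and 0 rose and 18 fell after scaling. Of 42 ribosomal protein genes without introns 21 fell and 21 did not pass, the falls led by RPP0 of the ribosomal stalk (-2.43 ± 0.27). Together the intronless ribosomal protein genes lay at -1.66 (adjusted p = 5.33e-33, and adjusted p = 0.626 with an estimated correlation), and 41 fell after scaling. Of 89 with introns 39 fell, 4 rose and 46 did not pass, with RPL22B (1.25 ± 0.26) and RPS9A (0.30 ± 0.26) among the rises. Together the intron-bearing ribosomal protein genes lay at -1.53 (adjusted p = 2.57e-43, and adjusted p = 0.626 with an estimated correlation), and 1 rose and 82 fell after scaling. For all 269 genes with introns 106 rose, 46 fell and the others did not pass, and this direction flipped after scaling to 19 rises and 121 falls. Together the intron-bearing genes lay at -0.65 (adjusted p = 3.12e-09, and adjusted p = 0.626 with an estimated correlation). Of 87 ribosome biogenesis genes 7 rose, 1 fell and 79 did not pass, which flipped after scaling to 0 and 36. Camera set that list lower than other genes, while its own median and an uncalled fry test pointed up (fry adjusted p = 0.849). Together the ribosome biogenesis genes lay at -0.90 (adjusted p = 1.22e-10, and adjusted p = 0.929 with an estimated correlation). Of 10 histone genes CSE4, the centromeric variant, rose (0.80 ± 0.26) and 9 did not pass. Together the histone genes lay at -1.18 (adjusted p = 0.000168, and adjusted p = 0.626 with an estimated correlation), and 1 rose and 8 fell after scaling. Of 76 small nucleolar RNAs 46 fell, with a median log2 change of -1.41 before any shift, among them SNR59 (-3.71 ± 0.54) and SNR5 (-3.60 ± 0.60). In 10 bins of mean expression the median change went from 1.17 in the lowest to -0.43 in the highest, where 56 genes rose and 219 fell. Every gene named here for xrn1 except STE2, MFA1 and STE6 kept its call whichever 1 library was left out. The count of calls fell in each of these fits, furthest without wild type 3. Of all calls picked by the naming rule for xrn1, a minority was lost without at least 1 library.

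**Figure D3:**
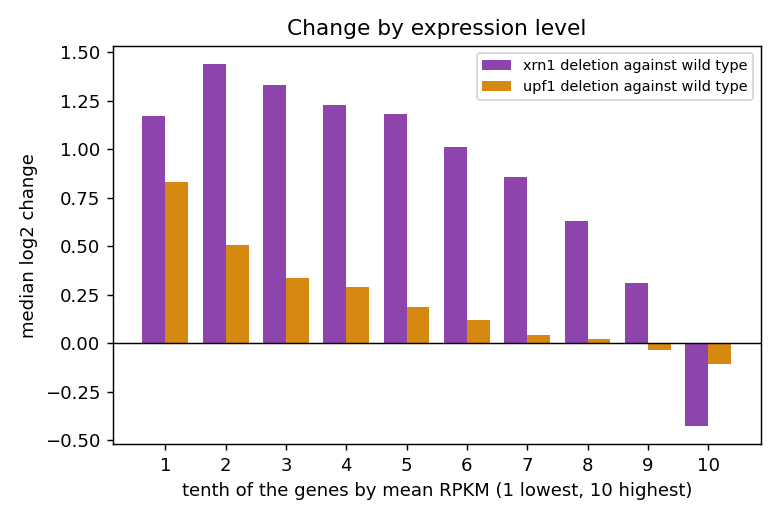
Median log2 change against the wild type (bars) for genes in 10 equal bins of mean RPKM, for the xrn1 deletion (purple) and the upf1 deletion (orange), as deposited and without rescaling. For xrn1 the median falls from 1.44 in bin 2 to -0.43 in the highest.

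Loss of UPF1 raised 860 genes and lowered 6 (2 libraries against 2), 775 and 4 of them by at least 2-fold, with the median of all genes at 0.15, to which gene values here are relative. The highest included COS12, a subtelomeric DUP family gene (log2 3.55 ± 0.45, adjusted p = 0.00143), DAL7, malate synthase of allantoin degradation (log2 3.35 ± 0.23, adjusted p = 0.000355), which went from 8.38 ± 1.47 to 105 ± 11.3 RPKM (SD, n = 2 each), and PET18 (3.18 ± 0.27). Of 18 known nonsense-mediated decay substrates 9 rose and 9 did not pass (10 rose when adjusted over the list alone), the rises led by STN1 (2.66 ± 0.24), EST2 (2.39 ± 0.26) and MAK31 (1.66 ± 0.23). Together the decay substrate genes lay at 0.72 (adjusted p = 5.14e-06, and adjusted p = 0.768 with an estimated correlation; fry adjusted p = 0.0224). NMD4, a decay cofactor, rose as well (2.04 ± 0.24). Of 15 telomere maintenance genes 7 rose and 8 did not pass (7 when adjusted over the list alone), with STN1, EST2 and EST3 (1.57 ± 0.25) among the rises. Together the telomere genes lay at 0.52 (adjusted p = 0.0012, and adjusted p = 0.811 with an estimated correlation). Of 210 genes within 20 kb of an end 116 rose and 94 did not pass (146 rose when adjusted over the list alone), and of 68 subtelomeric family genes 30 rose and 38 did not pass (47 when adjusted over the list alone). Together the chromosome-end genes lay at 1.33 (adjusted p = 9.2e-23, and adjusted p = 0.768 with an estimated correlation). Together the subtelomeric family genes lay at 1.28 (adjusted p = 6.71e-16, and adjusted p = 0.768 with an estimated correlation). Of 26 meiosis and sporulation genes 17 rose and 9 did not pass (20 when adjusted over the list alone), the rises including RED1, of the meiotic chromosome axis (2.71 ± 0.36), and SPS4 (2.69 ± 0.27). Together the meiosis genes lay at 1.42 (adjusted p = 2.49e-10, and adjusted p = 0.768 with an estimated correlation). Of 10 galactose genes 6 rose and 4 did not pass (8 when adjusted over the list alone), the rises including GAL1, galactokinase (1.90 ± 0.38), which lost its call without wild type 3 (1.77, unshifted) and without upf1 2 (1.89). Together the galactose genes lay at 1.06 (adjusted p = 0.00571, and adjusted p = 0.811 with an estimated correlation). Genes of low mean expression rose more with the upf1 deletion. Before any shift, the median change was 0.829 in the lowest of 10 bins of mean expression and -0.107 in the highest. The lists given here were not tested against genes of matched expression.

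Genes with introns outside the ribosomal proteins rose in part with the upf1 deletion: 36 of 180 rose and 144 did not pass (42 rose when adjusted over the list alone), the rises including NBL1, a chromosomal passenger protein (2.18 ± 0.29). Together the other intron-bearing genes lay at 0.14 (adjusted p = 0.0256, and adjusted p = 0.832 with an estimated correlation), and at 0.09 and not called without wild type 1. Among ribosomal protein genes with introns RPL22B rose (log2 1.41 ± 0.26, adjusted p = 0.00453) and 88 did not pass. Of 27 iron regulon genes 4 rose, 2 fell and 21 did not pass (6 rose and 3 fell when adjusted over the list alone), and 4 were higher and 3 lower after scaling. Together the iron genes lay at -0.23 (adjusted p = 0.132, and adjusted p = 0.846 with an estimated correlation). Among them the reductase gene FRE2 rose (2.25 ± 0.27), while FET3, the ferroxidase (log2 -2.25 ± 0.60, adjusted p = 0.0487), and FTR1, the iron permease (log2 -1.66 ± 0.36, adjusted p = 0.0224), fell, and these falls were lost without wild type 1 (-1.99 and -1.45, unshifted), wild type 3 (-2.21 and -1.58) or upf1 2 (-1.29 and -0.91). After scaling to the same median log ratio 844 genes were higher and 61 lower. The count of calls was 290 without upf1 2 (2 of them lower), 529 without upf1 1 (23 lower) and 381 without wild type 3 (18 lower). COS12, DAL7, PET18, STN1, EST2, EST3, MAK31, NMD4, RED1, SPS4, NBL1, RPL22B and FRE2 kept their calls in each of these fits. Of all calls picked by the naming rule for upf1, nearly as many were lost without at least 1 library as were kept. No list direction given here for upf1 turned on scaling.

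**Figure D4:**
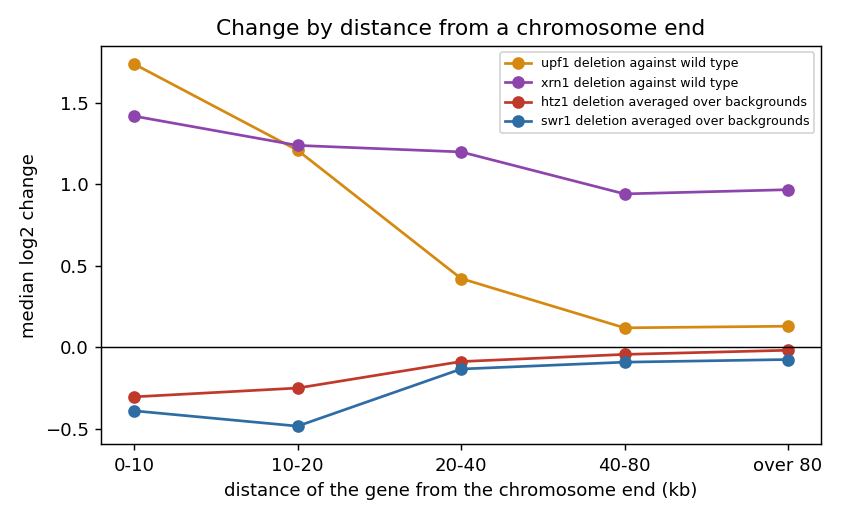
Median log2 change (points, joined by lines) of genes grouped by distance from the nearest chromosome end in kb, for the upf1 (orange) and xrn1 (purple) deletions against the wild type and the htz1 (red) and swr1 (blue) deletions averaged over backgrounds, as deposited. Within 10 kb the medians are 1.74, 1.42, -0.31 and -0.39, and beyond 80 kb they are 0.13, 0.97, -0.02 and -0.08.

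The prp43 DAmP library (1 library against 2) showed 28 higher and 0 lower genes, with 255 genes at an unadjusted p under 0.05 and 31 calls with voom. By the fixed lists, 5 of them were cell wall genes and 7 were ergosterol genes. DAN1 stood at 314 RPKM against 2.49 ± 2.47 (SD, n = 2) in the wild type (log2 6.82 ± 0.62, adjusted p = 0.00288, relative to a median of all genes of -0.115), PBI1 at 372 against 5.29 ± 2.42 (6.06 ± 0.36) and TIR1 at 4410 against 172 ± 17.3 (4.79 ± 0.44). Of 36 cell wall and flocculation genes 5 rose and 31 did not pass (5 when adjusted over the list alone), the mannoproteins DAN1, DAN4 (5.51 ± 0.60), TIR1 and TIR3 (4.12 ± 0.49) among the rises. Together the cell wall genes lay at 0.26 (adjusted p = 1.22e-06, and adjusted p = 0.812 with an estimated correlation). Of 24 ergosterol biosynthesis genes 7 rose and 17 did not pass (21 rose when adjusted over the list alone), the rises including ERG28, a scaffold of the pathway (3.06 ± 0.36), ERG3, sterol desaturase (2.68 ± 0.24), and ERG25, a sterol demethylase (2.44 ± 0.33). Together the ergosterol genes lay at 1.505 (adjusted p = 2.2e-47, and adjusted p = 0.0784 with an estimated correlation; fry adjusted p = 0.0143). None of 24 sulfur and methionine genes passed (4 rose when adjusted over the list alone), nor did any of 19 phosphate genes (9 fell when adjusted over the list alone). Together the sulfur genes lay at 0.51 (adjusted p = 6.48e-11, and adjusted p = 0.122 with an estimated correlation). The methionine marker MET17 was nearly absent in this library but not in the wild type, so its loss cannot be told apart from the allele here. Together the phosphate genes lay at -0.73 (adjusted p = 3.8e-09, and adjusted p = 0.812 with an estimated correlation). None of 87 ribosome biogenesis genes passed, among them NSR1, a pre-rRNA processing protein (log2 -1.13). Together the ribosome biogenesis genes lay at -0.78 (adjusted p = 6.52e-24, and adjusted p = 0.824 with an estimated correlation). Without wild type 3 there were 25 higher and 9 lower genes. Without wild type 1 or with no filter on low values there were 17 calls, and without wild type 1 ERG25 (2.27, unshifted) lost its call, as it did without wild type 3 (2.37).

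**Figure D5:**
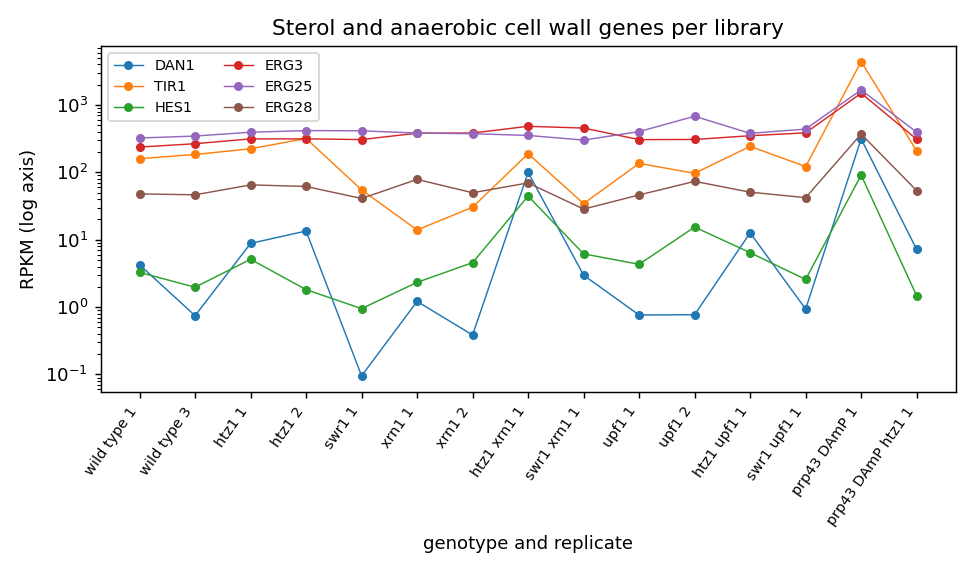
RPKM (log axis) of DAN1, TIR1, HES1, ERG3, ERG25 and ERG28 in each of the 15 libraries (points, joined by lines for each gene). In prp43 DAmP, DAN1 stands at 314 and TIR1 at 4410 RPKM, and in prp43 DAmP htz1 at 7.17 and 209.

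Whether the htz1 effect differed between backgrounds was tested as an interaction, in which each double mutant has a single library. For xrn1 no gene passed with limma, with 153 genes at an unadjusted p under 0.05 and 0 calls with voom, and the smallest p belonged to HUG1, induced by DNA damage (log2 3.12 ± 0.59, adjusted p = 1), DAN1 (3.87 ± 0.80) and IMD2, of guanine nucleotide synthesis (3.22 ± 0.71). The 38 nuclear respiratory chain genes, none called, lay at -0.82 (adjusted p = 1.01e-31, and adjusted p = 0.734 with an estimated correlation). For upf1 no gene passed either, with 79 at an unadjusted p under 0.05 and 0 with voom, and the smallest p belonged to YOR302W (log2 2.25 ± 0.53, adjusted p = 0.957, relative to a median of all genes of 0.243) and COS12 (-2.82 ± 0.71). The 68 subtelomeric family genes (-0.67; adjusted p = 6.36e-18, and adjusted p = 0.614 with an estimated correlation) and the respiratory chain genes (-0.63; adjusted p = 8.36e-17, and adjusted p = 0.614 with an estimated correlation) held no call. Without wild type 3 each of these interactions had 17 calls (10 higher for xrn1, 9 for upf1), and that with upf1 had 1 without upf1 1. For prp43 DAmP 10 genes passed, all lower than the sum of the single effects, DAN1 (log2 -7.25 ± 0.88, adjusted p = 0.0387) and PBI1 (log2 -6.26 ± 0.51, adjusted p = 0.00367) among them, as DAN1 stood at 314 RPKM in prp43 DAmP and 7.17 in prp43 DAmP htz1. Of 24 ergosterol genes ERG3 fell (-2.59 ± 0.35) and 23 did not pass (16 fell when adjusted over the list alone), of 36 cell wall genes 3 fell and 33 did not pass (5 fell when adjusted over the list alone), and of 24 sulfur genes none passed (2 fell when adjusted over the list alone). Together the ergosterol genes lay at -1.44 (adjusted p = 9.91e-53, and adjusted p = 0.0595 with an estimated correlation). Together the cell wall genes lay at -0.39 (adjusted p = 9.46e-11, and adjusted p = 0.682 with an estimated correlation). Together the sulfur genes lay at -0.75 (adjusted p = 7.7e-16, and adjusted p = 0.0595 with an estimated correlation). The MET17 marker was unequal between the libraries compared, being nearly absent in htz1 2 and both prp43 DAmP libraries. This count was 1 (PBI1) with a pseudocount of 0.1 or with no filter on low values, 16 with a pseudocount of 5, 5 without wild type 1 or htz1 1 and 29 without wild type 3 (9 of them higher), and ERG3 lost its call without wild type 1 (-2.51) and without either htz1 library (-2.59). DAN4 (-6.57) and TIR1 (-4.93) lost theirs without wild type 1 and PAU2 (-3.95) without htz1 1, and 3 further genes in both of these fits, whereas DAN1 and PBI1 kept theirs. In none of the 11 comparisons did any list keep its call with an estimated correlation between genes. Of the 35 lists, fry called 26 for xrn1, 7 for upf1, 1 for htz1 and 1 for prp43 DAmP against the wild type. It called 2 for averaged htz1, 4 for averaged swr1 and 4 for htz1 against swr1. For swr1 against the wild type and for each interaction it called 0. Camera at the preset correlation called 8 to 20 in each comparison.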

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

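The tests of oxygen-repressed genes and of the libraries that carry the htz1 deletion with prp43 DAmP or with xrn1 were chosen after the result was seen, and the interaction itself was planned. Between prp43 DAmP and the wild type the effect of the htz1 deletion differed, by the interaction test, for 10 genes, all with lower values than the single effects sum to: DAN1 (log2 -7.25), PBI1 (-6.26), DAN4 (-6.22), YPR145C-A (-5.41), TIR1 (-5.03), PAU2 (-4.02), SET4 (-3.60), YSR3 (-3.29), YMR316C-B (-3.10) and ERG3 (-2.59). With a pseudocount of 0.1 or with no filter on low values only PBI1 of these was called. Without wild type 1 DAN4 (-6.57), TIR1 (-4.93), SET4 (-3.64), YSR3 (-3.54), YMR316C-B (-3.33) and ERG3 (-2.51) were not called. Without htz1 1 PAU2 (-3.95), SET4 (-3.33), YSR3 (-3.03), YMR316C-B (-3.01) and ERG3 (-2.59) were not, and without htz1 2 YMR316C-B (-3.18) and ERG3 (-2.59) were not, while DAN1, PBI1 and YPR145C-A kept their calls in each of these fits. Without wild type 3 all 10 kept theirs among 29 calls, of which 9 were higher. Over the 28 genes called in prp43 DAmP, the median log2 difference from the wild type was 2.97 in that library and -0.191 in prp43 DAmP htz1, although PRP43 was low in both. These genes were chosen by their rise in that 1 library, so the value of 2.97 follows from the choice. Lower values in any other library would be likely for the same reason. The interaction calls rest on the same single library. For a shortage of oxygen in the culture, a median log2 rise of at least 1 was predicted in 5 oxygen-repressed genes. Their median was -0.316, from ANB1 (-0.51), AAC3 (-0.316), COX5B (-0.551), CYC7 (0.23) and HEM13 (0.699). The prediction was not met for these genes in 1 library, but DAN1, an anaerobic cell wall gene, was high there. A shortage of oxygen therefore stays open. A lower PRP43 level by itself may still account for the rise, because the value of -0.191 rests on 1 library that also lacks HTZ1. A need for HTZ1 in this response stays open for the same reason, and values of some of the genes stand against it: htz1 xrn1, which also lacks HTZ1, held DAN1 at 99.9 and HES1 at 44.5 RPKM. Of the same 28 genes 10 stood at least 1 log2 unit above the xrn1 libraries there, with a median difference of 0.454. The ergosterol genes among the 28 did not, lying between -0.81 (ERG5) and 0.334 (ERG3). TIR1 stood 3.134 above the xrn1 libraries but only 0.141 above the wild type. A lower PRP43 level and a need for HTZ1 cannot be told apart from a difference between single cultures of the 2 genotypes.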

How the results depend on the processing

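Fits with limma voom and those by rDNA share were chosen after seeing the data, the estimated correlation was not among the alternatives fixed in advance, and the others were planned. Called named genes kept direction and call in 3806 gene and setting pairs, lost the call in 776 and reversed in 11, and called lists in 807, 18 and 3. Counts of calls that moved by more than 1.5 times were as follows, and the cause was not tested unless stated. Ranges for leaving out 1 library are given for every comparison, whether or not the count moved that far. With no filter on low values, where 6659 genes were tested, htz1 against the wild type had 1 call (4 in the report), swr1 0 (2), prp43 DAmP 17 (28) and the htz1 interaction with prp43 DAmP 1 (10), which also had 1 with a pseudocount of 0.1 and 16 with 5, where swr1 had 0. A mean of at least 10 RPKM, which left 5932 genes, gave 105 for averaged swr1 (260). Scaling gave 2387 for xrn1 (4220) and 364 for averaged htz1 (125), and voom 0 for swr1 and 17 for htz1 against swr1 (26). The additive model gave 268 for averaged htz1, and 259 with the rDNA share as a term. For averaged swr1 it gave 364, within 1.5 times of 260, and 6 with that term. Without the 2 rDNA-rich htz1 libraries averaged htz1 had 13 calls, and in only the 5 rDNA-rich libraries htz1 against swr1 had 146. Leaving out 1 library gave 1 to 27 calls for htz1, 2640 to 4118 for xrn1, 290 to 885 for upf1, 2 to 18 for swr1, 17 to 34 for prp43 DAmP, 30 to 86 for averaged htz1, 43 to 282 for averaged swr1, 19 to 29 for htz1 against swr1, 0 to 17 for the interactions with xrn1 and with upf1, and 5 to 29 for that with prp43 DAmP; fewer samples enter each of these fits, and 6 such fits could not be made because they leave out the only library of a genotype.

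With the replicate number as a term (replicate block), htz1 against the wild type had 1 call and averaged htz1 8, and genes with introns turned to 0.0283. Replicate deviations correlated at 0.515 between wild type and htz1, -0.129 between wild type and xrn1 and 0.02 between wild type and upf1. They correlated at -0.273 between htz1 and xrn1, 0.129 between htz1 and upf1 and 0.187 between xrn1 and upf1. The numbers therefore do not pair the samples across all of these groups, although the wild-type and htz1 libraries deviated together. For genes with introns in averaged htz1 (-0.0797), the value was -0.0158 without ribosomal protein genes, -0.0994 with matched genes, -0.0797 with an estimated correlation (p = 0.422), -0.0798 after scaling (p = 0.0546), 0.0202 without the rDNA-rich htz1 libraries, -0.0135 with the rDNA share as a term and -0.1223 to -0.026 with 1 library left out; against the wild type it was -0.083 (p = 0.000471) with matched genes and -0.2042 to 0.1705 with 1 left out, 0.1425 without htz1 1. Ribosomal protein genes with introns in averaged htz1 turned to 0.0522 with the replicate block and 0.0303 without the rDNA-rich htz1 libraries, and MATalpha-specific genes against the wild type to 0.0683 without wild type 1 (-5.867 without wild type 3). After scaling, NAM7 (-0.1043), ERG8 (-0.0375), ERG27 (-0.1613), ERG7 (-0.2243), BUD21 (-0.0102) and CAN1 (-0.1752) reversed in xrn1, by the shift of all genes. With the rDNA share as a term YLR154W-A (-0.5406), YLR154W-B (-0.3926), TAR1 (-0.3494), YLR154C-G (-0.377) and YLR154W-F (-0.5033) reversed in averaged swr1, which the term fixes in advance because the share is summed over these frames. Depth limits low genes most: 1 read per kilobase was worth 0.0174 RPKM in prp43 DAmP and 0.14 in swr1 upf1.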

Other observations

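The tests of chance for the phosphate genes, of SWR1 deposition, of the rDNA share and of mating type were chosen after the results were seen; the counts of splits, the scaling test and the tests of shared reads were planned.

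The 76 small nucleolar RNAs had a median log2 change of 0.48 in the htz1 deletion averaged over backgrounds, with SNR76 called (1.12; not called at 1.07 without wild type 1, 1.15 without htz1 xrn1 and 0.89 without htz1 upf1), and of 0.41 in the swr1 deletion, with 4 called higher, against -1.41 in xrn1. Of 7 other noncoding RNAs 4 were higher in xrn1 (median 1.83) and 3 in upf1 (0.51). NMD4, a decay cofactor (log2 -0.60 ± 0.12), and STN1, of the telomere cap (-0.51 ± 0.11), which rose in xrn1 and upf1, fell in the averaged htz1 comparison, as did ARP6, a subunit of the SWR1 complex (-0.66 ± 0.11). STN1 lost this call whichever 1 of the 12 libraries was left out (-0.46 to -0.55), NMD4 in 9 of those fits (-0.55 to -0.65), and ARP6 without htz1 xrn1 (-0.65) or either prp43 DAmP library (-0.64). DAN1, at 99.9 RPKM, and HES1, an oxysterol-binding protein, at 44.5 RPKM, were also high in htz1 xrn1, the only library besides prp43 DAmP where DAN1 exceeded 13.5 or HES1 15.4 RPKM. Across 6467 genes, log2 effects of the deletions in backgrounds that share no library correlated with Pearson's r of 0.526 to 0.56 between swr1 effects (3 pairs), 0.022 to 0.457 between htz1 effects (6 pairs) and 0.176 to 0.511 between htz1 and swr1 effects (9 pairs), where genes are not independent replicates. Every swr1 library was rich in rDNA sequence, so the agreement of swr1 effects cannot be assigned to the deletion. The pair at 0.511, htz1 in upf1 with swr1 in xrn1, also joined 2 rDNA-rich libraries.

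For the counts of called genes, other splits of the same libraries within backgrounds were fitted. For the averaged htz1 deletion 1 of 100 splits, the real one, gave 125 calls and the highest other gave 1, so a chance division is argued against. For the swr1 deletion 1 of 27 gave 260 and the highest other 0, which argues the same way. That share, 3.7%, is the smallest that 27 splits allow. The real swr1 split also follows the rDNA share and, in the xrn1 and upf1 backgrounds, mating type. The split test cannot separate these from the deletion. For htz1 against swr1 the 12 splits within backgrounds are too few for a share under 0.05, with 26 calls in the real one and 0 in the highest other. Dividing the same 7 libraries across backgrounds, 2 of 34 splits gave as many calls, so chance is not excluded by that test, and the highest other gave 413 (1 further split could not be fitted). That split sets htz1 2, htz1 upf1, htz1 xrn1 and swr1 upf1 against the rest, several times the real count, which points to a structure of the samples; in the wild-type and xrn1 backgrounds it parts libraries poor and rich in rDNA, and within the 5 rDNA-rich libraries the real comparison had 146 calls with 1 residual degree of freedom.

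Lower phosphate genes in the libraries without HTZ1 were weighed against 3 technical explanations. Chance differences between cultures are argued against, since only 1 split, the real one, had a list mean as low and the lowest other was -1.114; scaling between libraries is argued against by a median of -1.369 after scaling. Reads shared by PHO11 and PHO12 do not account for the whole, as the other 17 members had a median of -0.908 with 9 called lower, although the bound of -1 set in advance was narrowly missed. A fall through loss of H2A.Z deposition by SWR1 may or may not apply: 1 of 12 splits separated the htz1 from the swr1 libraries as far, the lowest other being -0.636, and 12 splits cannot give a share under 0.05. The swr1 libraries themselves had a list mean of -0.415 (3 of 27 splits as low; exact one-sided p = 0.111), short of the bound set for that explanation. In the wild-type background swr1 (6.131) lay between the wild-type libraries (6.471 and 5.716), while swr1 xrn1 (6.18) lay below the xrn1 libraries (6.492 and 6.906) and swr1 upf1 (5.535) below the upf1 libraries (6.512 and 6.087). The hypothesis that phosphate genes depend on H2A.Z in a way not shared with SWR1 was found on these data, and unequal phosphate supply between cultures stays untested.

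Lower genes within 20 kb of chromosome ends in the swr1 libraries had several open explanations. With the rDNA share as a term the list value moved from -0.366 to -0.232, so libraries rich in rDNA sequence may account for part of it. Mating type could not be excluded: wild type 1, with alpha-specific transcripts, lay 0.371 above wild type 3, against the fall, but the htz1 replicates differed by 0.472. Shared reads within subtelomeric families may add to it, since the 155 genes in no listed family had a median of -0.301 against -0.431 for all 210, with 29 of them called lower. Loss of SWR1 itself, the biological explanation in the design, cannot be told apart from these with 3 libraries that are all rDNA-rich and of one mating type.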
